A study of Mus musculus with 24 samples.

How the data were processed

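The series holds 24 liver samples from male BALB/c mice, bought at 6 weeks of age and fed the control diet or 0.1%, 0.5% or 1.0% quercetin for 14 days, with 6 mice per group. Per the labels' protocols, total RNA of each mouse was made into biotin-labelled cRNA and hybridized to an Affymetrix mouse array. The authors deposited 1 table of intensity values for 45101 probe sets, on a linear scale with no value below 0. The software, background correction and probe summary behind the deposited intensity values are not given in the sources used here. Array medians ran from 4.78 to 7.58 and trimmed means, with 2% trimmed at each end, from 24.2 to 44.9. Over the 24 arrays the shift of the spike-in control probe sets followed the shift of the array (Pearson r = 0.78, permutation p = 3e-05; Spearman rho = 0.666; r = 0.768 without the 2 arrays farthest from the median), so the table had not been scaled between arrays.

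Before the data were examined, the plan was to test the deposited values as log2(value + 1) and to use quantile normalization as an alternative. After the array medians and spike-ins were seen, and before any group was tested, quantile normalization of log2(value + 1) became the main setting and values without normalization between arrays the alternative. This change raised most counts of genes, and the counts without normalization stand beside the main ones. Without it the median of all genes differed from control by 0.11 at 0.1%, 0.15 at 0.5% and 0.0541 at 1.0% on the log2 scale. Folds are on the log2(value + 1) scale, which understates changes of dim genes.

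Gene names came from the platform annotation: 34945 probe sets had 1 gene symbol and were used, 932 had several and were left out, and 9211 were not listed. Of the probe sets used, 34741 had a gene ID in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Each of 18193 genes was represented by its probe set with the highest mean over the 24 arrays. Genes of the fixed lists without such a probe set were not analysed here, and 551 of 616 list genes had a value.

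All 24 arrays entered 1 fit per test in limma 3.58.1 under R 4.3.3, with eBayes and two-sided tests at a Benjamini-Hochberg adjusted p of 0.05, for each dose against control, each pair of doses, any difference among the groups and the slope over dose. The 32 gene lists fixed before the data were examined, covering diet and drug responses, liver metabolism, stress, inflammation, the clock, sex bias and other cell types, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with at least 3 members measured. The mixed test of fry was read after the data were seen and passed 1 list at 0.1% and 5 at 0.5%, with 2 and 0 without 4 arrays. With fry's directional test the neutrophil list passed at 1.0% (adjusted p = 0.0458) and for the slope (adjusted p = 0.0295). Genes were named by a rule fixed at the same time: for each dose against control and the slope, up to 10 rises and 10 falls among those passing, or, with fewer than 5 passing, those and the 5 smallest p, and from lists up to 4 members with the smallest p at 1.0%. Clone names were skipped. Naming genes between doses was added after their values were seen. No other probe set of a named gene went the opposite way at an adjusted p under 0.05.

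The fits were tested on simulated arrays with 50 genes changed by each of 4 sizes among 18193. For 1.0% against control, 12% of genes changed by 0.5 log2, 48% of those changed by 1, 80% of those changed by 2 and 98% of those changed by 3 were recovered. For the slope the shares were 18%, 56%, 88% and 100%. False calls were 7 of 126 and 3 of 134. In simulated lists at 1.0%, 2 of 2 shifted lists and 0 of 30 others were called. The simulated genes were drawn independently, while the estimated correlation in the measured heat shock list was 0.634. The simulated lists therefore do not address false calls among correlated genes. Alternatives were the handling of probe sets, filters on dim or little varying probe sets, normalization, eBayes options, array weights, each array left out, the replicate number as a block, a fold of at least 1.5 and fits with 2 groups. A pseudocount of 16 for counts, leaving out 4 arrays apart on the first principal component or 2 arrays with high 18S signal, and sets of 3 replicates as a random effect (consensus correlation 0.0445 for groups and 0.0565 for the slope) were added after the data were seen.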

Results

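Liver RNA was measured in 24 male BALB/c mice with 1 Affymetrix expression array per mouse. The mice fell into 4 diet groups of 6. The control group ate AIN93G, a purified rodent diet, and the other groups ate the same diet with 0.1%, 0.5% or 1.0% quercetin, a flavonol found in many plant foods, for 14 days. The design asks which liver transcripts differ from control at each dose and which follow the dose. The deposited intensities had array medians from 4.78 to 7.58, and the number of arrays limits the precision of each value. Values below are quantile-normalized log2(intensity + 1) over 18193 genes, differences carry their standard error (SE) from limma over the 24 arrays, and p-values are adjusted with the Benjamini-Hochberg method unless stated. Mice were housed 3 per cage and the cage of each mouse was not used here, so an effect of the cage cannot be separated from that of the diet.

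At 1.0% quercetin, 3 genes rose and 1 gene fell against control. Gpr146, an orphan G protein-coupled receptor gene, rose 2.02-fold (log2 difference 1.01, SE 0.15, adjusted p = 0.00607), from 6.24 ± 0.20 in control to 7.25 ± 0.32 (log2, SD, n = 6). Csad, which encodes an enzyme of taurine synthesis, rose 2.03-fold (log2 1.02, SE 0.15, adjusted p = 0.00607), and Dnase2a, a lysosomal DNase gene, rose 2.27-fold (log2 1.18, SE 0.18, adjusted p = 0.00607). These genes lay above the control mean in 6, 6 and 6 of 6 arrays of the 1.0% group. Carlr passed as lower (adjusted p = 0.00607) near the floor, at a signal brighter than 8.59% of the probe sets used, so no size is given, and with a pseudocount of 16 its adjusted p was 0.0742 (range over 13 alternatives 0.0078 to 0.149). It lay below the control mean in 6 of 6 arrays. Next by p-value, without passing, were Sdr39u1 (log2 -0.53, adjusted p = 0.0544), Pnrc1 (-0.65, 0.193), Zeb2 (-0.92, 0.222), Arhgap44 (-0.85, 0.222) and Fbln1 (1.63, 0.222). Without normalization between arrays limma passed 0 genes at 1.0%, and centred on array medians 1 rose and 1 fell. Without the 4 arrays that stood apart on the first principal component 0 passed. In the normalized values 1623 of 18193 genes (8.92%) had an unadjusted p under 0.05, and 4 passed. Without control replicate 5 the count was 7. Without the least variable probe sets 12 rose and 1 fell at 1.0%, sharing 0 of the 4 genes. Gpr146, Csad and Dnase2a had no probe set left under that filter and were not tested.

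**Figure D1:**
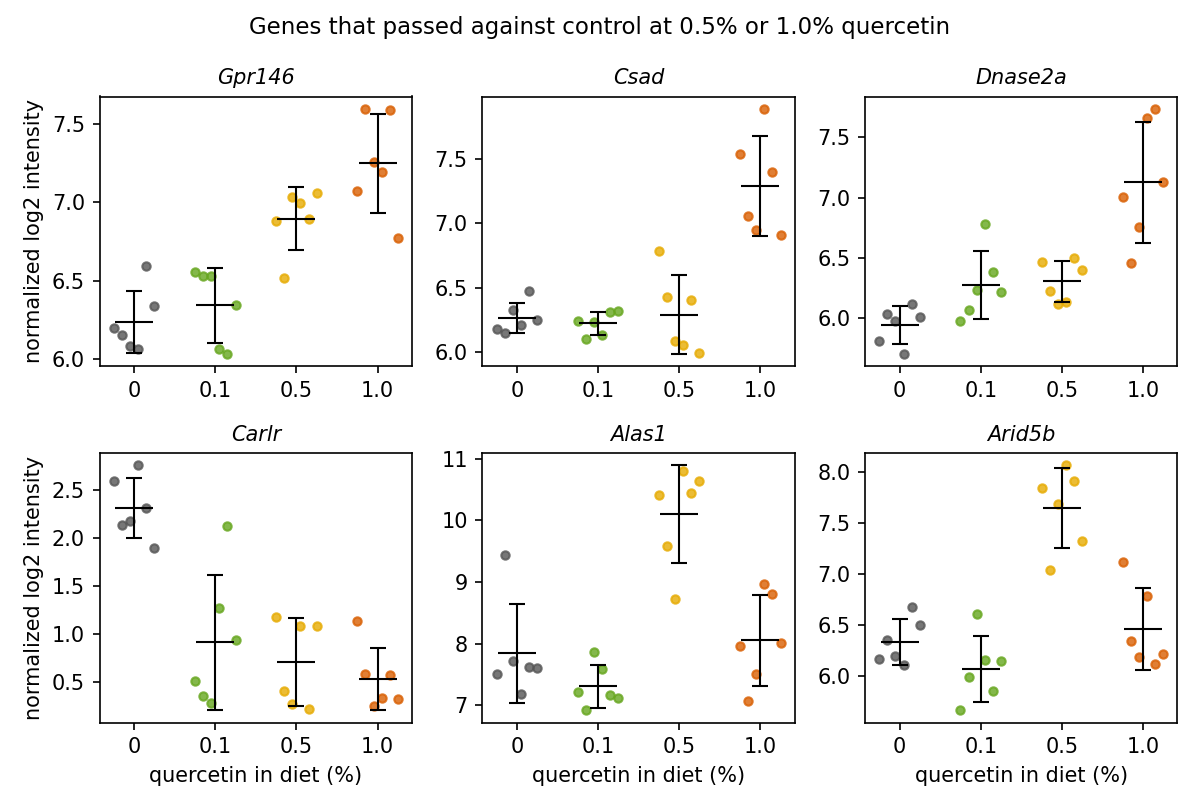
Normalized log2 intensity (y axis) against the quercetin content of the diet in percent (x axis) for the genes that passed against control, with 1 point per mouse and the group mean with its SD (n = 6). Gpr146 lies at 6.24 in control and 7.25 at 1.0%, and Alas1 at 7.84 in control and 10.10 at 0.5%.

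Among the 4 of 32 gene lists that passed at 1.0%, the acute phase list stood higher than other genes and the bile acid and sterol handling list lower. The acute phase list had 22 of 26 members above control (camera, adjusted p = 1.76e-07; adjusted p = 0.672 with an estimated correlation). It holds mostly genes whose products the liver secretes in inflammation, but also Mt1, Mt2 and Socs3, whose products act inside cells. None of its members passed over all genes tested, and 7 rose when adjusted over the list alone. Mt1 and Mt2, the metallothionein genes, were higher than control by 4.75 (SE 1.17) and 4.92 (SE 1.31) on the log2 scale, Saa2 by 2.21 (SE 0.68) and Socs3, a feedback inhibitor of cytokine signalling, by 2.11 (SE 0.47), with adjusted p from 0.223 to 0.365. The neutrophil marker list was also higher, with 10 of 11 members above control (adjusted p = 0.00131; adjusted p = 0.127 with an estimated correlation). Its members with the smallest p were Lcn2 (log2 1.97), which the acute phase list also holds, S100a8 (0.95), S100a9 (0.78) and Camp (0.49), and none passed over all genes or over the list alone. Camp lay near the floor, at 2.49 or less in each array, so its size is uncertain. Without the 4 arrays that stood apart, the acute phase list kept an adjusted p of 6.88e-05 (0.533 with an estimated correlation) and the neutrophil list 0.00214 (0.0479), and without replicate 2 of the 1.0% group 7 lists passed. Without those 4 arrays the heat shock list (adjusted p = 0.0203; adjusted p = 0.733 with an estimated correlation) and the unfolded protein response list (0.00058; 0.533) newly passed as lower at 1.0%, as did the male-biased list (0.0425; 0.543), and the cholesterol synthesis list (0.0151; 0.733) as higher. Centred on array medians, the respiratory chain (0.00108), amino acid and urea (0.0301) and male-biased lists (0.0301) newly passed as lower (adjusted p). Of 22 bile acid and sterol handling genes, 15 lay below control (adjusted p = 0.0186; adjusted p = 0.672 with an estimated correlation), and the call was lost without those 4 arrays (adjusted p = 0.389) and without normalization between arrays (0.064). Nr0b2, the nuclear receptor SHP that represses bile acid synthesis, differed by -1.05 (SE 0.25) and Abcb11, the bile salt export pump, by -0.35 (SE 0.0883), and both fell when adjusted over the list alone. The uptake transporters Slc10a1 (-0.25) and Slco1b2 (-0.20) did not pass.

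Of the lists tied to diet and xenobiotics, the PPAR-alpha list passed at 1.0%. Of 35 targets of PPAR-alpha, the receptor that drives fatty acid oxidation, 29 lay above control with a median log2 difference of 0.12 (adjusted p = 0.00237; adjusted p = 0.83 with an estimated correlation). This call was lost without normalization between arrays (adjusted p = 0.113) and with arrays centred on their medians (0.132). Pex11a, a peroxisome division gene, was 0.49 above control (SE 0.12) and passed when adjusted over the list alone, with Eci2 at 0.36, Cpt1a at 0.28 and Plin2 at 0.33 not passing. The Nrf2 target list did not pass (adjusted p = 0.75), with a median of -0.0407 against a mean of 0.0715, and its members Ugdh (0.66), Ephx1 (0.32), Aox1 (0.25) and Gstm4 (0.24) had adjusted p of 0.365 or above. In the mixed test of fry, which counts members of either direction and was read after the values were seen, 3 of 32 lists passed at 1.0%, namely the Nrf2 (adjusted p = 3.65e-05), circadian clock (3.65e-05) and acute phase lists (0.0121). The Nrf2 call was kept without the 4 arrays that stood apart (2.64e-06) and centred on array medians (0.00317) and lost without normalization between arrays (0.45). The number of lists was 1 without normalization and 13 without the 4 arrays. Neither the Ahr list (adjusted p = 0.75), with Nfe2l2 (-0.40), Cyp1b1 (0.70), Tiparp (0.48) and Cyp1a2 (-0.0923), nor the CAR and PXR list (adjusted p = 0.288), with Cyp3a44 (-1.13), Ces2a (-0.29), Aldh1a1 (0.19) and Cyp3a13 (0.29), passed. Of these, Cyp3a44 and Ces2a fell when adjusted over the list alone. Fatty acid and triglyceride synthesis genes did not pass as a list (adjusted p = 0.122), with the desaturase gene Scd1, which fell when adjusted over the list alone, at -0.66, the elongase gene Elovl6 at -0.65, Lpin1 at 2.09 (7.11 or more in replicates 4 to 6 against 6.14 or less in replicates 1 to 3) and Cidea at 1.10. Cidea lay near the floor in control, at 0.96 or less in each array, so its size is uncertain. Cholesterol synthesis genes did not pass over all arrays (adjusted p = 0.187), with Sqle at 0.99, Idi1 at 0.74, Srebf2 at 0.49 and Msmo1 at 0.44. Without the 4 arrays the adjusted p of that list was 0.0151, and 0.733 with an estimated correlation.

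At 0.5% quercetin, 2 genes rose and 1 fell against control. Alas1, the first enzyme of heme synthesis, rose 4.77-fold (log2 2.25, SE 0.39, adjusted p = 0.0464), and Arid5b, a DNA-binding regulator, rose 2.49-fold (log2 1.31, SE 0.20, adjusted p = 0.0199). Carlr passed as lower near the floor (adjusted p = 0.0464), and with a pseudocount of 16 this call was lost (adjusted p = 0.107). Alas1 and Arid5b lay above the control mean in 6 and 6 of 6 arrays of the 0.5% group, and Carlr below it in 6. The next 5 genes by p-value were Fbln1 (log2 1.95), H2-T3 (-1.75), Cish, a feedback inhibitor of cytokine signalling (2.40), Cacna1c (-1.39) and Mtrr (0.95), with adjusted p from 0.0558 to 0.125. Cacna1c lay near the floor, at 2.43 or less in each array, so its size is uncertain. H2-T3 was dim in the 0.5% group, at 2.51 or less in each array, so its size is uncertain too. Without normalization between arrays 5 genes rose and 0 fell at 0.5%, centred on array medians 5 rose and 2 fell, and without the 4 arrays that stood apart 1 gene passed, sharing 0 of the 3. Without the least variable probe sets 16 rose, sharing 1 of the 3, and with replicates 1 to 3 and 4 to 6 of each group as sets with a shared random effect 1 gene passed. In limma the fit with the 2 groups compared and the fit with the replicate number as a block each passed 0 genes. With 1 array left out the call of Alas1 held in 8 of 24 fits (largest adjusted p = 0.164), that of Arid5b in 20 and that of Carlr in 12. The count was 0 without control replicate 1 or 4 or replicate 4 or 5 of the 0.5% group, 1 without control replicate 5 or 6 or replicate 1 or 4 of the 0.1% group, 6 without replicate 6 of the 0.1% group and 5 without replicate 2 or 3 of the 1.0% group.

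The 0.5% group had 7 of 32 gene lists past the threshold, and none with an estimated correlation. The acute phase list was higher (23 of 26 members above control, adjusted p = 7.77e-08; adjusted p = 0.467 with an estimated correlation), and 10 members rose when adjusted over the list alone. Mt1 stood at 3.18 (SE 1.17) and Socs3 at 2.00 (SE 0.47). Mt1 was 8.99 or more in replicates 4 to 6 against 5.91 or less in replicates 1 to 3. Heat shock proteins, the chaperones of protein folding, had 16 of 18 members above control (adjusted p = 2.3e-07), the unfolded protein response 16 of 22 (adjusted p = 0.00143) and the immediate early genes 12 of 14 (adjusted p = 6.31e-05), each with adjusted p = 0.467 with an estimated correlation. In the immediate early list 4 members rose when adjusted over the list alone, and in the other lists 0. Examples were Hspb1 (0.64), Xbp1, a transcription factor of the unfolded protein response (0.72), and Myc (1.44), none of which passed over all genes. The neutrophil markers were higher (adjusted p = 0.00424; adjusted p = 0.378 with an estimated correlation), with S100a8 at 1.52 and Lcn2 at 2.02, and both rose when adjusted over the list alone. Fatty acid and triglyceride synthesis genes were lower, with 22 of 31 below control (adjusted p = 0.00891; adjusted p = 0.653 with an estimated correlation), although Lpin1 stood at 2.33 (6.76 or more in replicates 4 to 6 against 5.72 or less in replicates 1 to 3). Bile acid and sterol handling genes were lower too (adjusted p = 0.00114; adjusted p = 0.467 with an estimated correlation), with Nr0b2 at -0.76. Without the 4 arrays that stood apart, the calls of the fatty acid list (adjusted p = 0.61), the immediate early list (0.713) and the neutrophil list (0.184) were lost. Without normalization between arrays those of the fatty acid (0.112) and bile acid lists (0.545) were lost, and centred on array medians these (0.0814 and 0.255) and the neutrophil list (0.0575).

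At 0.1% quercetin no gene passed against control in limma, and 930 of 18193 genes, 5.11%, had an unadjusted p under 0.05. The 5 genes with the smallest p were Zfp458 (log2 -1.45), Klf10, an immediate early transcription factor gene (-1.05), Carlr (lower, near the floor), Lonrf3 (0.82) and Herpud1, a gene of the unfolded protein response (-1.11), with adjusted p from 0.152 to 0.351. Heat shock proteins were lower as a list, with 17 of 18 members below control (adjusted p = 0.00146; adjusted p = 0.819 with an estimated correlation). Unfolded protein response genes were lower as well, with 16 of 22 below control (adjusted p = 0.00221; adjusted p = 0.819 with an estimated correlation). Adjusted over the list alone, 0 heat shock and 1 unfolded protein response genes fell, the latter Herpud1. Without control replicate 2 the number of lists was 0 and without replicate 4 or 6 of the 0.1% group 4, and without replicate 5 of that group 1 gene passed. In control replicate 2 the heat shock genes Bag3, Dnajb1 and Hspb1 lay far above the other control arrays. Without normalization between arrays the circadian clock list newly passed as lower (adjusted p = 0.0333, against 0.0589).

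Along the dose, 7 genes rose and 11 fell (slope in log2 per 1% quercetin). Counts of slopes under other settings ran both lower and far higher, as the section on processing gives. Socs3 had the steepest rise, 2.45 (SE 0.47, adjusted p = 0.0343), and lay above the control mean in 6 of 6 arrays at 1.0%, and Gpr146 the smallest p (1.03, SE 0.13, adjusted p = 0.000645). Csad (1.01), Dnase2a (1.04), Fbxo31 (1.06), Gin1 (1.04) and Pex11a (0.61) also rose. Trhr, the receptor for thyrotropin-releasing hormone, passed as lower near the floor, at a signal brighter than 8.94% of the probe sets used, and with a pseudocount of 16 its call was lost (adjusted p = 0.0656), so no size is given. Nr0b2 fell by 1.22. Arhgap44 fell by 1.02, Lnx2 by 0.88, Coq8a, which acts in coenzyme Q synthesis, by 0.82, Tsga10 by 0.82, Pnrc1 by 0.75, Tmcc1 by 0.71, Slc30a10, a manganese exporter, by 0.63, Trim2 by 0.58 and Sdr39u1 by 0.53. Without the least variable probe sets, where other probe sets represent them, the slopes of Tsga10 (0.30) and Sdr39u1 (0.57) turned upward without passing. The PPAR-alpha list sloped upward (28 of 35 members positive, adjusted p = 0.000328; adjusted p = 0.591 with an estimated correlation). So did the acute phase (3.89e-08; 0.572 with an estimated correlation), neutrophil (0.00122; 0.113) and heat shock lists (0.0191; 0.623), all as adjusted p. Fatty acid synthesis (adjusted p = 0.0205; adjusted p = 0.602 with an estimated correlation) and bile acid genes (0.0138; 0.572) sloped downward. Of the respiratory chain, 30 of 32 genes had negative slopes with a median of -0.0441 (adjusted p = 0.0205; adjusted p = 0.602 with an estimated correlation). In the mixed test of fry 9 lists passed for the slope (3 without normalization), the Nrf2 list among them (adjusted p = 2e-06; 0.139 without normalization), where 5 members rose and 2 fell when adjusted over the list alone. In the fatty acid list 12 members fell and 4 rose when adjusted over the list alone. Without normalization between arrays limma passed 0 slopes, and the respiratory chain call was lost (adjusted p = 0.31). In the normalized values 1985 of 18193 genes (10.9%) had an unadjusted p under 0.05, and 18 passed. Without the 4 arrays that stood apart, the PPAR-alpha (3.82e-06; 0.469 with an estimated correlation), acute phase (5.12e-05; 0.469) and neutrophil lists (0.00435; 0.0515) passed at the preset correlation only, the fatty acid (0.0993), bile acid (0.345) and respiratory chain lists (0.412) did not, and the heat shock list turned downward (0.895), all as adjusted p. Centred on array medians the amino acid and urea list newly passed as sloping downward (adjusted p = 0.0356). Without the least variable probe sets 22 slopes rose and 1 fell, sharing 1 of the 18 genes. Csad, Dnase2a, Gpr146, Fbxo31, Gin1, Arhgap44, Lnx2, Coq8a, Pex11a and Slc30a10 had no probe set left under that filter and were not tested. With the sets of 3 arrays as a random effect 7 slopes passed. With 1 array left out the calls of Gpr146, Csad, Dnase2a and Pnrc1 held in 24 of 24 fits. Those of Arhgap44 (23), Sdr39u1 (23), Fbxo31 (21), Tmcc1 (17), Trim2 (17), Nr0b2 (15), Trhr (14), Slc30a10 (13), Socs3 (12), Lnx2 (12), Tsga10 (11), Pex11a (7), Gin1 (6) and Coq8a (5) held in fewer. The count of 18 was 8, 7 and 8 without control replicates 1 to 3, 8, 8, 11, 9 and 9 without replicates 1 to 5 of the 0.1% group, 43 without replicate 6 of the 0.5% group, and 55, 61, 4, 10 and 11 without replicates 1, 2, 3, 5 and 6 of the 1.0% group.

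More genes passed at 0.5% or 1.0% against 0.1% than against control. At 1.0% against 0.1%, 21 genes were higher and 25 lower, and Dbp, a clock-controlled transcription factor, led with 3.96 (SE 0.58, adjusted p = 0.00302, above the 0.1% mean in 6 of 6 arrays). Among genes chosen after the values were seen, the other large rises were Socs3 (2.30), St3gal5 (1.87), Klf10 (1.34) and Tef, a clock-controlled relative of Dbp (1.13), and Nr1d2, the clock repressor REV-ERB beta, rose by 1.06. Falls included Celsr1 (-1.54), Lonrf3 (-1.43), G6pc, the glucose-6-phosphatase gene (-1.40), and Itga5 (-1.28), and the clock repressor gene Cry1 fell by 1.27. At 0.5% against 0.1%, 26 genes were higher and 13 lower, led by Dbp (3.06), Socs2 (2.98), Alas1 (2.79), Onecut1 (2.67) and Slc25a30 (1.61) upward and H2-T3 (-1.71), Ppfia4 (-1.58), Tnfaip2 (-1.56), Ppp1r3c (-1.04) and Rnf125 (-1.0) downward. H2-T3 and Ppfia4 were dim, at signals brighter than 44.4% and 46.4% of the probe sets used. With a pseudocount of 16 they passed at -0.43 each (adjusted p = 0.0211 and 0.0454), so the sizes of both genes between doses are uncertain. At 1.0% against 0.5%, Csad (1.00), Ppfia4 (1.73) and Saal1 (0.49) were higher and Arid5b lower (-1.19). Without normalization between arrays 3 genes rose and 3 fell at 1.0% against 0.1%, 19 rose and 2 fell at 0.5% against 0.1%, and limma passed 0 at 1.0% against 0.5%. In the normalized values of that last comparison 1127 of 18193 genes (6.19%) had an unadjusted p under 0.05, and 4 passed. Centred on array medians, 8 rose and 12 fell, 45 rose and 4 fell, and 0 rose and 1 fell. With the sets of 3 arrays as a random effect the counts were 22, 7 and 0 at 1.0% against 0.1%, 0.5% against 0.1% and 1.0% against 0.5%.

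These counts moved when arrays were left out. At 1.0% against 0.1% the count of 46 was 20, 19, 25 and 18 without replicates 1, 2, 3 and 5 of the 0.1% group and 25, 24, 24 and 22 without replicates 3 to 6 of the 1.0% group. At 0.5% against 0.1% the count of 39 was 6, 5, 6, 7 and 4 without replicates 1, 2, 3, 5 and 6 of the 0.1% group and 22, 59, 10, 6 and 10 without replicates 1, 2, 4, 5 and 6 of the 0.5% group. At 1.0% against 0.5% the count of 4 was 0 without any of replicates 3 to 6 of the 0.5% group or replicate 5 of the 1.0% group. It was 1 without control replicate 1, replicates 2 or 4 of the 0.1% group, replicate 1 of the 0.5% group or replicates 1, 3 or 6 of the 1.0% group, 2 without its replicate 4 and 8 without control replicate 2. At 1.0% against 0.1% the calls of Dbp, St3gal5, Klf10, Tef, Nr1d2, Lonrf3 and Cry1 held in 24 of 24 such fits, and those of G6pc (17), Celsr1 (16), Itga5 (15) and Socs3 (13) in fewer. At 0.5% against 0.1% those of Alas1 and Tnfaip2 held in 24, and those of Dbp (16), Ppfia4 (16), Ppp1r3c (16), H2-T3 (15), Onecut1 (15), Slc25a30 (15), Rnf125 (15) and Socs2 (9) in fewer.

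**Figure D2:**
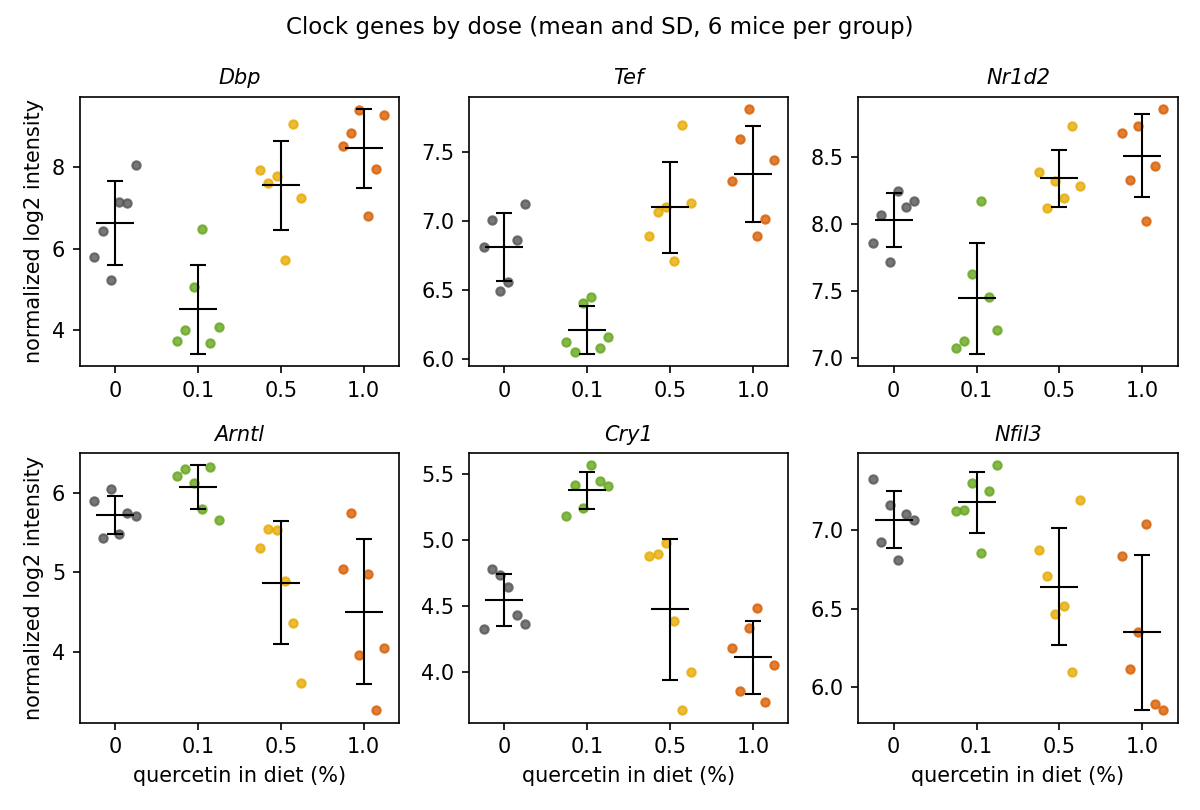
Normalized log2 intensity (y axis) of 6 clock genes against the quercetin content of the diet in percent (x axis), with 1 point per mouse and the group mean with its SD (n = 6). Dbp lies at 6.62 in control, 4.50 at 0.1% and 8.47 at 1.0%, and Cry1 at 4.55, 5.38 and 4.11.

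The test for any difference among the 4 groups passed 33 genes, among them Csad (adjusted p = 0.00384), Lonrf3 (0.00384), Arid5b (0.00384) and Alas1 (0.00572), without normalization between arrays it passed 4, and without replicate 2 of the 0.1% group 17. Without the least variable probe sets it passed 32, sharing 3 of the 33. Csad and Lonrf3 had no probe set left under that filter and were not tested. The 0.5% and 1.0% comparisons shared 1 called gene, Carlr, but they also share the control arrays. Independent lists of these sizes would share 5.5e-05 genes downward, and with the controls split into separate sets of 3 no gene passed in both. Across genes the log2 differences of these doses correlated at r = 0.564, and genes are not independent replicates. Unchanged groups against shared controls gave a median of 0.509 and a highest value of 0.665, so 0.564 lies within their range. The covariance of these doses was 0.0838 against a median of 0.0648 in the unchanged groups, and with split controls the median r was 0.112.

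Mt2 varied widely within the higher doses. It lay between 3.33 and 4.95 in the control arrays, between 3.82 and 12.02 at 0.5% and between 6.10 and 12.11 at 1.0% (log2). The highest values belonged to replicates 4 and 6 of the 0.5% group and replicates 4 and 5 of the 1.0% group, which also had scores over 20 on the first principal component of all genes (9.15% of the variance). Replicates 4 to 6 lay above replicates 1 to 3 in both groups, with Mt2 of 8.36 or more against 4.69 or less at 0.5% and 9.77 against 8.38 at 1.0%. Over all genes, arrays of the same set of 3 correlated more than arrays of the other set of their group (difference in mean r 0.0441, exact p = 0.0017, 10000 splits). The difference was 0.0799 in these 12 arrays (exact p = 0.020, 100 splits) and 0.00841 in the control and 0.1% groups (exact p = 0.080, 100 splits), a comparison chosen after the values were seen. None of 5 array measures, among them brightness and the 3' to 5' signal of control probe sets, passed between a quercetin group and control (exact permutation tests over 924 splits, smallest adjusted p = 0.0974, n = 6).

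**Figure D3:**
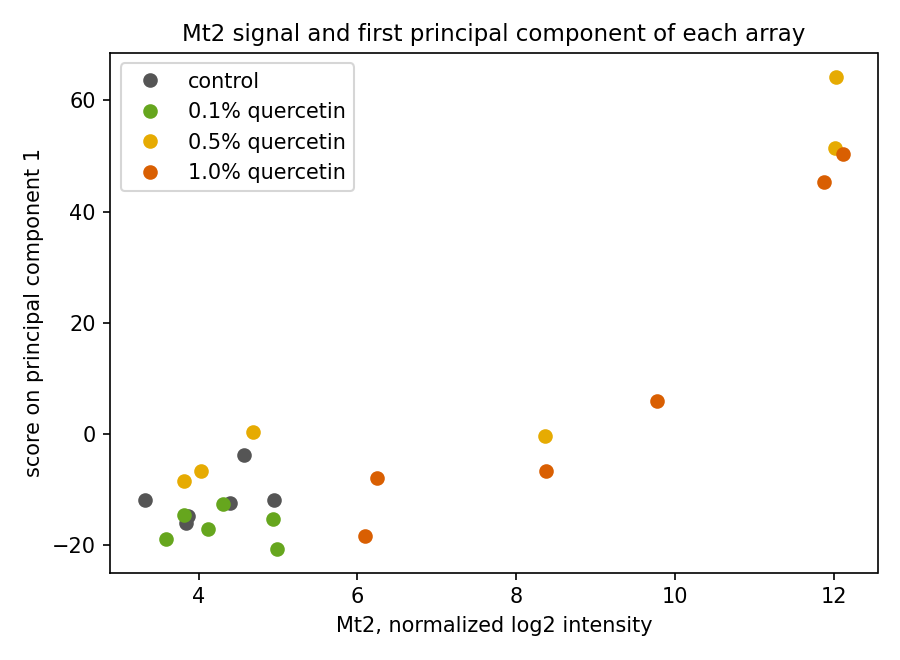
Score of each array on the first principal component (y axis, no unit) against its Mt2 signal (x axis, normalized log2 intensity), with 1 point per mouse and colours for the diet groups. The 4 arrays with scores over 20 have Mt2 of 11.88 to 12.11, and the control arrays lie at 4.95 or below.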

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

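The tests of dose order, sampling time, metallothionein against array quality, sets of 3 replicates and the Carlr signal were chosen after those results had been seen.

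An index of 9 clock-output genes minus 5 genes of the opposite phase, taken from textbook knowledge, was -0.75 log2 against control at 0.1% (exact p = 0.0281, n = 6), 1.36 at 0.5% (exact p = 0.00433) and 1.70 at 1.0% (exact p = 0.00216, the smallest 924 splits can give). The index summarizes a pattern already seen in the same arrays, so these p-values describe that pattern and add no separate support. The difference between 1.0% and 0.1% kept 0.983 of its size with brightness and 3' to 5' signal as covariates, which argues against these as the whole cause. These p-values take arrays as independent, but the index of replicates 4 to 6 lay above that of replicates 1 to 3 in control (-0.96 or more against -1.41 or less) and at 0.5% (0.0436 against -0.25), though not at 0.1% or 1.0%, so an effect of the cage or of handling in sets stays open, and a monotone response was not tested apart from the pattern itself. Output and opposite-phase genes moved against each other (ratio -0.832), which is what a shift of clock phase would give. The labels used here give no sampling times, so a difference in time of day between groups may account for the pattern, and it cannot be told apart from an effect of the diet.

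Mt1 and Mt2 were higher in replicates 4 to 6 than in replicates 1 to 3 of the 0.5% and 1.0% groups, and with no cage in the labels used here an effect of the cage or of handling mice in sets stays open and was not tested. Over those 12 arrays the neutrophil markers rose with metallothionein by 0.0768 log2 per log2 (95% interval 0.0273 to 0.126, the highest upper bound of 9 lists of other cell types), which argues against RNA from such cells as the main source. The largest correlation with a quality measure, in absolute size, was 0.387 (actin 3' minus 5', permutation p = 0.22; -0.697 without the 2 arrays farthest from the median), and its interval leaves RNA integrity open. Slc30a1, another metal-responsive gene, gave r = -0.322 (rho = -0.434, permutation p = 0.30), which leaves a metal response open. The mean of Tsc22d3, Sgk1 and Tat, targets of the glucocorticoid receptor, gave r = 0.633 (permutation p = 0.0256, adjusted over 6 relations 0.154; rho = 0.573, permutation p = 0.0553; r = 0.743 without the 2 arrays farthest from the median), so a stress hormone response may contribute as a hypothesis that fails the correction.

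Carlr was lower at 0.5% and 1.0%. Its probe set lies near the floor, and with a pseudocount of 16 its adjusted p at 1.0% was 0.0742, so noise at low signal may account for the call. An effect of the diet on Carlr stays open.

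In 420 tests of 6 arrays for a single array far from the others, 18 were found, 4.29% of them, where chance gives about 1 in 20. The tests are not independent, because correlated genes recur on the same arrays, so that rate does not show that each is chance. In the control group these were Alas1 in replicate 2 (9.44, nearest 7.72), Bag3 in replicate 2 (7.65, nearest 6.16), Dnajb1 in replicate 2 (9.03, nearest 7.49), Fbln1 in replicate 3 (3.39, nearest 1.76), Hspb1 in replicate 2 (7.05, nearest 5.38) and Myc in replicate 4 (3.91, nearest 2.66). Alas1 and the heat shock genes Bag3, Dnajb1 and Hspb1 were thus all high in control replicate 2, the array without which 0 lists passed at 0.1%. In the 0.1% group these were Lpin1 in replicate 6 (3.76, nearest 4.72), St3gal5 in replicate 2 (6.09, nearest 5.74) and the log2 trimmed mean in replicate 6 (4.82, nearest 5.17). In the 0.5% group these were Gpr146 in replicate 2 (6.52, nearest 6.88), Gstm4 in replicate 6 (7.04, nearest 7.31), Idi1 in replicate 1 (8.75, nearest 7.87), Ppp1r3c in replicate 6 (9.77, nearest 8.71) and Trim2 in replicate 3 (6.92, nearest 6.46). In the 1.0% group these were Cox6c in replicate 5 (10.71, nearest 10.98), Dusp1 in replicate 5 (7.29, nearest 8.39), Eci2 in replicate 2 (9.38, nearest 9.69) and the mean correlation with its own group in replicate 2 (0.911, nearest 0.921).

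The 18S ribosomal RNA control probe set, which is not among the genes tested, gave a log2 signal of 11.26 in replicate 1 of the 0.5% group and 10.04 in replicate 6 of the 1.0% group, above the highest control array at 8.56.

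Other splits of the arrays were counted for each test, with 100 splits each, the real one included. For genes at 0.5% (3, 1 of 100 splits as large, highest other 2), 1.0% (4, 1 of 100 splits as large, highest other 3), 1.0% against 0.1% (46, 1 of 100 splits as large, highest other 1), 0.5% against 0.1% (39, 1 of 100 splits as large, highest other 2), any group (33, 1 of 100 splits as large, highest other 2) and the slope (18, 1 of 100 splits as large, highest other 2), the real split alone gave so many genes. This argues against chance for single arrays dealt at random. The tests were not corrected for their number, and the margin was small at 0.5% and 1.0%. Arrays within the sets of replicates 1 to 3 and 4 to 6 correlated more than between them, however (difference in mean r 0.0441, exact p = 0.0017). The sets were noticed after the values were seen, and the difference was 0.00841 in the control and 0.1% groups (exact p = 0.080). With such sets as a random effect 1 gene at 0.5%, 7 slopes, 22 genes at 1.0% against 0.1% and 7 at 0.5% against 0.1% passed, so chance differences between sets stay open. Chance could not be excluded for genes at 1.0% against 0.5% (4, 5 of 100 splits as large, highest other 351). That highest split set replicates 1, 3 and 5 of the 0.5% group and 1 to 3 of the 1.0% group against the rest, with the 4 arrays that scored over 20 on the first principal component on 1 side. At 0.1% (0, 100 of 100 splits as large, highest other 6) the real count is 0, so each split is as large by construction and the splits do not address chance. For gene lists chance could not be excluded at 0.1% (2, 44 of 100 splits as large, highest other 8), 0.5% (7, 13 of 100 splits as large, highest other 11), 1.0% (4, 15 of 100 splits as large, highest other 8) or for the slope (7, 12 of 100 splits as large, highest other 10).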

How the results depend on the processing

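The settings without 4 arrays or the 2 arrays with high 18S signal, the pseudocount of 16 for counts, sets of 3 replicates as a random effect, and the left-out arrays and median centring between doses were chosen after the data were seen. Counts of genes are given for 0.1%, 0.5% and 1.0% against control, any group and the slope. Every probe set tested gave 1 at 0.5%, and the mean of probe sets 7 at 1.0%. Without the dimmer probe sets the counts were 70 for any group and 111 for the slope, 115 at 1.0% and 90 at 0.5% against 0.1%. Without the least variable ones they were 16 at 0.5%, 13 at 1.0%, 32 for any group and 23 for the slope, which share 1 of 3, 0 of 4, 3 of 33 and 1 of 18 genes, with 0 lists at 0.1% and 3 for the slope. That filter left some called genes without a probe set, Gpr146, Csad and Dnase2a among them, so it did not test these. Without normalization the counts were 5 at 0.5%, 0 at 1.0%, 4 for any group, 0 for the slope, and 6, 0 and 21 for 1.0% against 0.1%, 1.0% against 0.5% and 0.5% against 0.1%, with 2 lists at 1.0%. Centred on medians they were 7, 2, 20 and 1 at 0.5%, 1.0%, 1.0% against 0.1% and 1.0% against 0.5%, with 4 lists at 0.5%. Trend and robust options gave 86 for any group and 85 for the slope, array weights 6 at 0.5%, and dose as its rank 3 slopes. Fits with the groups compared gave 0 at 0.5%, 1 at 1.0%, and 10, 0 and 7 between doses, with fewer arrays. The estimated correlation left 0 lists. Without the 4 arrays there were 1 gene at 0.5%, 0 at 1.0%, 0 at 1.0% against 0.5% and 10 at 0.5% against 0.1%, with 4, 7 and 3 lists at 0.5%, 1.0% and for the slope. Without the 2 arrays there were 7 at 1.0% and 24, 2 and 13 between doses. With sets of 3 replicates as a random effect there were 1 at 0.5%, 7 slopes, and 22, 0 and 7 between doses. The pseudocount of 16 gave 97 for any group, 103 slopes, 111 at 1.0% and 100 at 0.5% against 0.1%. With 1 array left out, counts ran from 0 to 1 at 0.1%, 0 to 6 at 0.5%, 4 to 7 at 1.0%, 17 to 49 for any group, 4 to 61 for the slope, 18 to 62 at 1.0% against 0.1%, 0 to 8 at 1.0% against 0.5% and 4 to 59 at 0.5% against 0.1%, and lists from 0 to 4, 6 to 9, 3 to 7 and 5 to 8. Other counts stayed within 1.5 times, not always with the same genes. The cause was not tested except where fewer arrays were used. Of 6138 values of named genes under other settings, 5564 kept their side of the threshold with no turn beyond 1 SE, 362 no longer passed, 127 newly passed, 6 reversed and 79 that did not pass changed sign by more than 1 SE. With 1 array left out these were 10203, 467, 58, 0 and 0 of 10728. Most of these values had not passed in the main setting. The values kept are therefore mostly values that did not pass either way, and their share does not measure how often calls held. Saal1 at 1.0% against 0.1% was -0.47 with the mean of probe sets and -0.27 without the least variable ones, Sdr39u1 had slopes of 0.018 and 0.57, and Tsga10 a slope of 0.30 and 0.28 at 1.0% against 0.1%, because other probe sets represent them. Dim genes such as Carlr and Trhr are limited by signal over background.

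The replicate number as a block gave 0 genes at 0.5%, 0 at 1.0% against 0.5% and 21 at 0.5% against 0.1%. The numbers do not pair the arrays: 1 of 36 pairs with the same number correlated above 0.1, and 4 of 24 arrays correlated best with their own number.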

Other observations

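Clock genes differed in both directions at 1.0%. Of 19 measured, 6 rose and 3 fell at 1.0% when adjusted over the list alone, none passed over all genes, and the list as a whole did not pass in one direction (adjusted p = 0.492). In the mixed test of fry it passed at 0.1%, 0.5% and 1.0% (adjusted p = 0.000543, 0.0393 and 3.65e-05). Without the 4 arrays that stood apart the 0.5% call of this test was lost (adjusted p = 0.103). Those at 0.1% (0.000182) and 1.0% (4.71e-05) were kept. Usp2 was 2.30 (SE 0.56) and Per3 1.73 (SE 0.52) above control on the log2 scale, while Arntl, the clock activator BMAL1, differed by -1.21 (SE 0.35) and Nfil3 by -0.72 (SE 0.19). Usp2 and Per3 were dim in control, at 3.70 and 3.31 or less in each array, so their sizes are uncertain. For the slope, 7 rose and 5 fell when adjusted over the list alone.

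The lists of stress genes did not pass over all arrays at 1.0%. There Dnajb1 stood at -1.14, Fkbp4 at -0.23 and Bag3 at -0.52, while Hspb1 stood at 0.78, and the median of the heat shock list, which did not pass (adjusted p = 0.75), was 0.16 where its mean was -0.00626. The endoplasmic reticulum chaperone genes Pdia6 (-0.27), Pdia4 (-0.48) and Calr (-0.21) differed from control in the opposite direction to Xbp1 (0.67). Among immediate early genes Jun (-0.96), Dusp1 (-0.86) and Ccn1 (-0.44) lay below control, while the mean of Myc, named by the same rule, lay above it. None of these genes passed over all genes, and Dnajb1 and Jun fell when adjusted over their lists alone. In the respiratory chain Ndufa8 (-0.20), Cox6c (-0.13), Ndufb8 (-0.11) and Atp5g1 (-0.12) had the smallest p at 1.0% and did not pass, and the list passed as lower with arrays centred on their medians (adjusted p = 0.00108, against 0.0881).

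Marker lists of other cell types did not pass at 1.0%, apart from the neutrophil list. The adjusted p from camera was 0.975 for Kupffer cell and macrophage, 0.445 for lymphocyte, 0.75 for endothelial, 0.251 for stellate cell and fibroblast, 0.975 for bile duct, 0.789 for red cell, 0.75 for exocrine pancreas and 0.75 for adipocyte markers. Of the other lists, it was 0.408 for gluconeogenesis, 0.963 for glycolysis, 0.408 for conjugation and flavonoid efflux, 0.822 for antioxidant enzymes, 0.288 for amino acid and urea metabolism, 0.109 for male-biased and 0.408 for female-biased genes, 0.75 for the interferon response, 0.75 for p53 targets and 0.257 for cell proliferation. Centred on array medians the amino acid and urea list (0.0301) and the male-biased list (0.0301) passed as lower. The male-biased list also passed without the 4 arrays that stood apart on the first principal component (0.0425; 0.543 with an estimated correlation). In the conjugation list, which did not pass, 14 of 17 members lay below control. Without the 4 arrays that stood apart the direction of that list from camera was upward (adjusted p = 0.811).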
